A study of Homo sapiens with 4 samples.

How the data were processed

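RNA was measured on 4 Agilent 2-colour arrays. Per the labels, the Cy5 channel of each array held RNA of MCF-7 cells, a human breast cancer line, stably transfected with sst5TMD4, a truncated form of somatostatin receptor 5, and the Cy3 channel held 1 pool of RNA of MCF-7 cells with the empty vector. The labels describe the 4 cultures as independent passages. Every array had the same dye orientation, so an effect of the dyes on a single probe cannot be separated from an effect of the transfection. All 4 arrays lay on 1 slide, which left no slide to use as a block.

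Per the file headers, the arrays were of design 014868, a mouse design placed on the mouse genome build mm7, and 39217 of the 41174 different probes carried a description naming Mus musculus. The labels name a human line. Gene symbols are therefore those of the mouse probes as the files give them, and every level is a signal on a mouse probe, whatever RNA was bound. The human table of gene names held 186185 accessions, and 0 of the array's accessions were among them, so the names and coordinates of the files were kept. Coordinates are those of mm7, counted from 1. Exon and UTR annotation of mm7 was not used here.

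The deposited scanner files hold spot intensity per channel, not normalized, with the local background and the scanner's own quality calls, per the file headers. They also hold processed signals and a log10 ratio of Cy5 over Cy3 that Feature Extraction had made by background subtraction and its own dye normalization, per the file headers. The file headers name Feature Extraction 9.5.3.1, whereas the submitters' processing notes name version 10.0. The table of values deposited by the authors holds that log10 ratio, since each column lay within 0.00494 of the scanner's own ratio for the same array, with Cy5 over Cy3 as direction. Each of its columns had a median of 0.

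Mean spot signals were corrected with normexp on the median local background with an offset of 50, then normalized within each array by loess, with control spots given no weight, in limma 3.58.1 under R 4.3.3 with data.table (version 1.17.8). Spots marked as outliers by the scanner software were left out, spots of 1 probe were averaged, and saturated spots were kept. A probe was tested when it was well above background in at least 1 channel on at least 3 of the 4 arrays, which held for 16826 probes. The mean log2 ratio of Cy5 over Cy3 was tested against 0 with limma's lmFit and eBayes, with Benjamini-Hochberg adjustment and a threshold of 0.05. Because the control was 1 pool, the test leaves out the spread between control cultures. P-values measure the spread between these 4 arrays only. A further count took calls with a mean change of at least 2-fold. A sign-flip test over 4 arrays cannot give an exact 2-sided p below 0.125, so no such test was used.

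A gene was represented by its brightest tested probe. Among the 3855 genes with 2 or more tested probes, 164 had probes called in opposite directions. A probe not well above background in 1 channel on any array has only a bound there, given as an at-least fold. This bound set the mean of the bright channel against the higher of the dim probe's own signal and the lowest signal that was well above background, after loess and Aquantile scaling. It is open to dye bias. A probe saturated in a channel on all 4 arrays is given no fold.

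The genes to be named were fixed before the data were examined, as were 30 gene lists and the alternatives. Named were the 12 largest rises and 12 largest falls among called genes with the same sign on all 4 arrays and a signal well above background in both channels on all of them, up to 4 at-least folds per direction, up to 4 called members of each list with the largest change, and the somatostatin system. Genes without a usual symbol (RIKEN and predicted clones, LOC names and bare accessions) were skipped among the largest changes and the at-least folds, whatever their size. Genes named outside this rule, those of the runs of neighbouring genes among them, were chosen after their values were seen. Lists of at least 3 measured genes, 27 in all, were tested with camera in limma with an inter-gene correlation of 0.01, and beside it with an estimated correlation and with fry. These tests used the genes with a value on every array fitted, so counts of a list can hold 1 gene more than its test. The p of fry tests whether the genes of a list move, on balance, one way, and its mixed p tests for change in either direction. Neither compares a list with other genes.

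The order of genes along the chromosomes was scanned after the data had been seen. The median log2 ratio was taken over windows of 10 neighbouring genes, for 11643 placed genes, and compared with the lowest and highest windows of 1000 random orders. Intervals of shares are exact Clopper-Pearson intervals at 95%.

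The alternatives were no background correction, the Feature Extraction ratio, normexp with an offset of 0, median centring in place of loess, Aquantile scaling between arrays, the deposited value table, other filters on dim probes, another variance model, array weights, the mean of all probes of a gene, removal of a trend with probe GC content, limma's treat against a 1.5-fold limit, and each array left out in turn.

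The steps were tested on simulated data for this comparison. Of 16826 probes, 200 were given a change in the simulation. The test called 36 of 67 probes changed 1.5-fold, 56 of 67 changed 2-fold and 65 of 66 changed 3-fold, with 0 wrong signs, and 10 unchanged probes. When array 4 carried none of the change, 0 changed probes were called by limma. This does not carry over to the calls below. The simulation took each probe's spread over all 4 arrays, with array 4's distance in it, and changed few probes. In the data Mmp9 and Cxcl10 were called although they read -0.03 and -0.06 on array 4. Among 27 simulated lists over 11766 genes, the 1 list with a change, a log2 shift of 0.4, was found and 0 of the other 26 were called. Simulated genes varied independently, whereas the lists called below had estimated inter-gene correlations of 0.09 to 0.22. The simulation thus does not show how often camera calls unchanged lists in these data. A run of 30 neighbouring genes among 11643, shifted by -1 on the log2 scale, was found in full, with 10 further genes drawn in.

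Between 36.8% and 42.6% of probes were well above background in Cy3 and between 30.5% and 43.8% in Cy5. The number of arrays limits the precision of every value.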

Results

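RNA labelled as coming from MCF-7 cells, a human breast cancer line, was compared on 4 arrays. The Cy5 channel held RNA labelled sst5TMD4, from cells stably transfected with a truncated somatostatin receptor 5, and the Cy3 channel held a pool labelled empty vector. The title of the study places the receptor form in angiogenesis, and the comparison asks which transcripts differ between transfected and control cells. The arrays were of a mouse design, so the symbols are those of mouse probes. Cy3 signal was well above background for 16961, 17540, 16526 and 15132 of the 41174 probes on arrays 1 to 4, and Cy5 signal for 16500, 18027, 16542 and 12546. The log ratios of arrays 1 to 3 correlated across probes with Pearson's r of 0.85 to 0.93, whereas array 4 correlated with them at 0.38 to 0.45. Probes are not independent replicates.

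The targeted gene could not be followed, because 0 probes on the array carried the symbol Sstr5. Of the somatostatin system, 1 probe was bright enough to be tested. It lay in Sstr4, another somatostatin receptor gene, and gave a log2 ratio of 0.19 (SE 0.09, n = 4), with an adjusted p of 0.128 that did not pass the test. Its signal was well above background on 2 arrays in Cy3 and on 3 in Cy5, and its ratio on array 4 was 0.02. Left out in turn, arrays 1 to 4 gave adjusted p of 0.245, 0.295, 0.379 and 0.0275, with a ratio of 0.11 without array 3. The probe also passed at 0.68 with the Feature Extraction ratio (0.0372) and the deposited value table (0.0371), and at 0.18 with array weights (0.00159). A further Sstr4 probe, not tested, was well above background on 0 arrays in Cy3 and on 1 in Cy5. Probes for Sstr1, Sstr2, Sstr3 and the hormone gene Sst were well above background on 0 arrays in either channel, and Cort, which encodes cortistatin, on 2 arrays in Cy5 and 0 in Cy3. The direction of every ratio therefore rests on the labels.

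Among genes with a usual symbol, well above background in both channels on every array and with 1 sign throughout, the largest falls included neighbouring genes. Abcb1b, a multidrug efflux pump, fell by 2.84 on the log2 scale (SE 0.07, n = 4, adjusted p = 0.000123) in RNA labelled sst5TMD4, and Dbf4, the activator of the Cdc7 kinase, fell by 2.77 (SE 0.07). Crot, a carnitine acyltransferase, fell by 2.58 (SE 0.06), Ankib1 fell by 2.37 (SE 0.10), the calcium-binding protein gene Sri fell by 2.12 (SE 0.10) and Abcb4, a phospholipid transporter, fell by 2.08 (SE 0.10). These 6 lie on mouse chromosome 5, with the Abcb1b probe at 8903569 to 8903628, Dbf4 at 8435133 to 8435192, Crot at 9004074 to 9004133, Ankib1 at 3696495 to 3696554, Sri at 8102238 to 8105213 and Abcb4 at 8996752 to 8996811 in mm7. The other falls were those of the smooth muscle actin gene Acta2 at -2.20, Slurp1 at -2.12, Tmem45a at -2.04, the cardiac actin gene Actc1 at -2.04, the cytokine gene Tslp at -1.76 and Emb at -1.74. Other probes read -2.34 and -1.05 for Abcb1b, -0.49 for Dbf4, -0.82 for Crot, -0.95 and -0.34 for Ankib1, -2.25 and 0.40 for Acta2 and -1.04 for Emb.

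The largest rises by the same rule lay on several chromosomes. Mmp3, which encodes the matrix protease stromelysin, rose by 2.17 on the log2 scale (SE 0.07, n = 4, adjusted p = 0.000242; chromosome 9, 7453874 to 7453933), and Lsr, a lipoprotein receptor gene, rose by 2.14 (SE 0.06, adjusted p = 0.000154; chromosome 7, 27897635 to 27897781). The bicarbonate transporter gene Slc4a7 rose by 1.90 (SE 0.07), Soat1, which encodes an enzyme that esterifies cholesterol, by 1.79 (SE 0.16), Ywhaz by 1.78 (SE 0.18), Stk25 by 1.74 (SE 0.25), Hmgb1-rs17 by 1.69 (SE 0.08), Taok1 by 1.65 (SE 0.08) and the sodium-proton exchanger gene Slc9a2 by 1.65 (SE 0.15). Other probes of Taok1 read -0.07 and 0.22, those of Soat1 0.30 and 0.64, and that of Ywhaz 1.07. Kdelr2, a receptor that returns proteins to the endoplasmic reticulum, had the highest mean at 2.37 (SE 0.51), with 4.46 on array 4 and 0.59 at its other probe. Ptprz1 averaged 2.32 (SE 0.50) with 0.30 on array 4 and read -0.65 and -0.64 at its other probes, and the syndecan gene Sdc4 averaged 1.68 (SE 0.32) with 2.93 on array 4 and 0.28 at its other probe.

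These 24 genes were chosen by a passing adjusted p and the same sign on all 4 arrays, so neither is a separate result. Their adjusted p ranged from 0.000123 to 0.0209 in limma. Under median centring in place of loess 0 of the 24 passed, and Kdelr2 (adjusted p 0.056 without array 1, 0.057 without array 2 and 0.091 without array 3), Ptprz1 (0.093, 0.078 and 0.097) and Tslp (0.081, 0.068 and 0.087) were lost when a single array was left out, as was Sdc4 without array 3 (0.075).

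**Figure D1:**
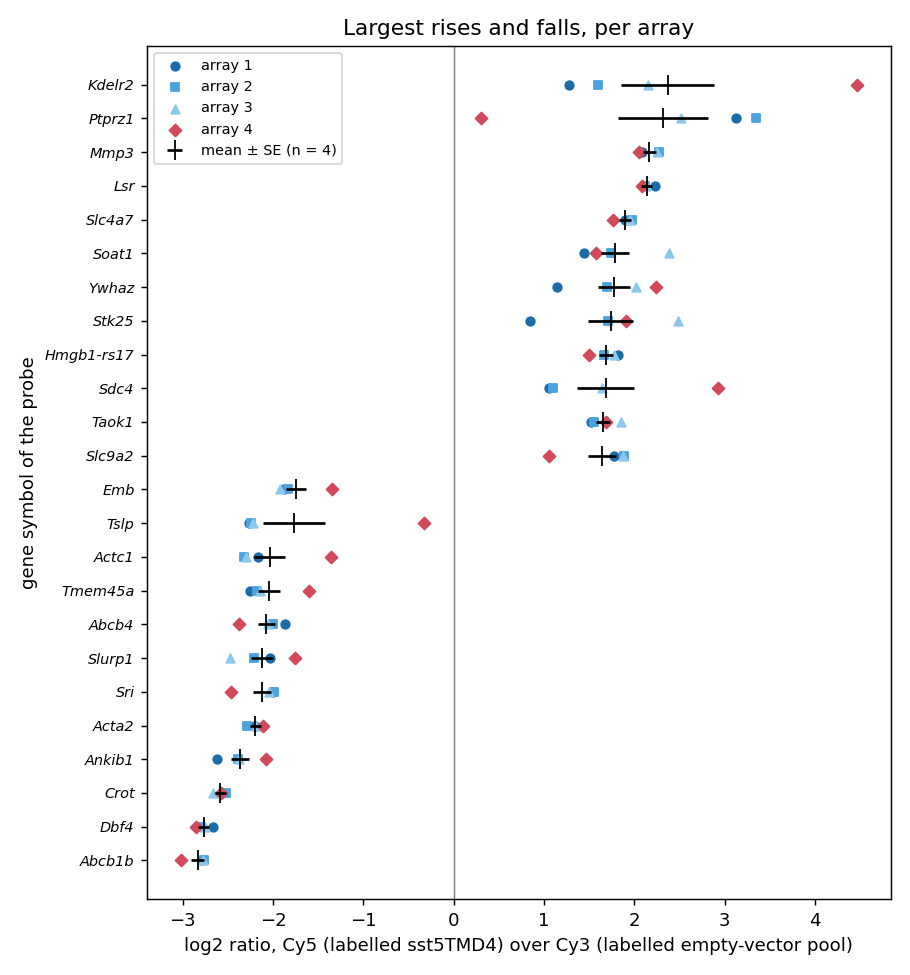
Log2 ratio of Cy5 (labelled sst5TMD4) over Cy3 (labelled empty-vector pool) for the 12 largest rises and 12 largest falls among genes with a usual symbol; each symbol is 1 array and the black cross is the mean with its standard error over 4 arrays. Array 4, in red, lies apart from arrays 1 to 3 for Kdelr2 (4.46), Ptprz1 (0.30) and Tslp (-0.33), and beside them for Mmp3 and Crot.

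Across the array, 5970 of 16826 tested probes passed the adjusted threshold, of which 2854 were higher and 3116 lower in RNA labelled sst5TMD4. Of the calls 5722, or 95.8%, had the same sign on all 4 arrays. A test against 0 over 4 arrays favours such probes, so that share is no separate measure of agreement between arrays. A change of at least 2-fold was called for 313 probes, 189 higher and 124 lower, and 250 of these were well above background in both channels on every array. Counted by gene, 1846 of 11813 were called higher and 2311 lower. The count was 1276 without array 1, 1013 without array 2, 1122 without array 3 and 10676 without array 4, and that of 2-fold changes was 181 without array 3 and 499 without array 4. Under median centring limma called 0 probes, with 3258 at an unadjusted p under 0.05 against 8340 here, and the Feature Extraction ratio gave 1199 changes of 2-fold, 535 higher and 664 lower.

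Some genes had a signal in 1 channel only, for which folds are lower limits open to dye bias. Sema3e, which encodes a guidance protein of axons and vessels, was at least 10.2-fold lower in RNA labelled sst5TMD4 (chromosome 5, 13734861 to 13734920, adjusted p = 0.0041). The collagen receptor gene Ddr2 was at least 2.88-fold lower, the neuropeptide gene Nmu at least 2.82-fold and the immunoproteasome gene Psmb8 at least 2.77-fold. Plau, which encodes urokinase, was at least 2.41-fold higher, the kinase gene Snf1lk at least 2.11-fold, Usf1 at least 1.59-fold and Rbms3 at least 1.42-fold. In all, 47 probes were well above background on every array in Cy3 and on none in Cy5, and 10 the other way round. The share of probes with Cy5 signal well above background was lowest on array 4, at 30.5%. Plau did not pass without array 3 (adjusted p 0.055).

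Of 21 measured hypoxia targets 12 fell, 1 rose and 8 did not pass in RNA labelled sst5TMD4, and of 15 glycolysis genes 10 fell, 1 rose and 4 did not pass. Camera gave an adjusted p of 0.0106 for the hypoxia targets and 0.0145 for glycolysis, and adjusted p = 0.655 with an estimated correlation for both lists, over the 20 and 14 genes with a value on all 4 arrays (Ldha, at 0.02, had 3). Both lists hold Aldoc, Hk2, Ldha, Pgk1 and Slc2a1, so they are not independent results. Adjusted over the list alone, 15 hypoxia targets changed, with a median log2 ratio of -0.31 over the 4 arrays (-0.30 with genes measured in 1 channel at their bound) and -0.13 on array 4. Ndrg1, a stress-response gene, fell by 1.10 (SE 0.08, n = 4), the aldolase gene Aldoc fell by 1.18 (SE 0.17, Cy5 above background on 3 arrays) and Pdk1, a kinase that restrains pyruvate oxidation, fell by 0.70 (SE 0.11) with -0.22 at its other probe. Bnip3 averaged -0.73 (SE 0.21) with 0.11 on array 4. Likewise 11 glycolysis genes changed over the list alone, with a median of -0.44, and -0.32 on array 4. The triose phosphate isomerase gene Tpi1 fell by 0.82 (SE 0.11), the hexokinase gene Hk1 by 0.80 (SE 0.10) and the pyruvate kinase gene Pkm2 by 0.77 (SE 0.13), while Aldoa, counted among the falls, was saturated in Cy5 on every array, which leaves its ratio open upward. Other probes read -0.13 and -0.01 for Hk1 and -0.68 for Pkm2. With arrays 1 to 4 left out in turn, 4, 3, 2 and 15 hypoxia targets fell and 1, 1, 1 and 3 rose, and 4, 4, 3 and 11 glycolysis genes fell. Ndrg1, Tpi1 and Hk1 passed with each array left out. Aldoc was lost without array 3 (adjusted p 0.052), Pkm2 without array 1 (0.055), and Pdk1 (0.052, 0.057 and 0.063) and Bnip3 (0.155, 0.147 and 0.156) without array 1, 2 or 3. Glycolysis had an adjusted p of 0.119 under median centring.

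Of 20 measured genes of the G2 and M phases 9 fell, 0 rose by limma and 11 did not pass (11 changed when adjusted over the list alone). Camera gave an adjusted p of 0.0145, and adjusted p = 0.655 with an estimated correlation. The list had a median of -0.30, and -0.14 on array 4. The cyclin gene Ccnb1 fell by 0.49 (SE 0.07, n = 4), the ubiquitin ligase partner Ube2c by 0.66 (SE 0.10), the cyclin gene Ccna2 by 0.80 (SE 0.17) and the spindle checkpoint gene Bub1b by 0.52 (SE 0.11). Ccna2 read -1.47 and Ube2c -1.02 on array 4, and other Ccnb1 probes -0.64 and -0.56. Of 20 S phase genes 6 fell and 0 rose by limma (4 adjusted over the list alone), among them Rrm1 at -0.50 (SE 0.09), Mcm5 at -0.55 (SE 0.17), Mcm2 at -0.50 (SE 0.14) and Dhfr at -0.47 (SE 0.10), with a list median of -0.05, and -0.23 on array 4. Other Dhfr probes read -0.55 and -0.17. When arrays 1 to 4 were left out in turn, 2, 2, 2 and 16 genes of the G2 and M phases fell. Of the S phase genes 0, 0, 0 and 6 then fell and 0, 0, 0 and 3 rose by limma, with a median of -0.10 without array 1, -0.11 without array 2 and -0.08 without array 3. The adjusted p in camera was 0.397 for the S phase genes, whose test direction turned under median centring (0.844). Under median centring the G2 and M phase genes had an adjusted p of 0.189, and of the 8 genes only Ccnb1 passed with each array left out. Ube2c was lost without array 3 (0.055), and Ccna2 (0.078, 0.060 and 0.070), Bub1b (0.084, 0.086 and 0.095), Rrm1 (0.057, 0.061 and 0.056), Mcm5 (0.137, 0.102 and 0.101), Mcm2 (0.132, 0.107 and 0.081) and Dhfr (0.085, 0.100 and 0.083) without array 1, 2 or 3.

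Of 12 measured NF-kB targets 6 rose in RNA labelled sst5TMD4, 0 fell by limma and 6 did not pass (6 changed when adjusted over the list alone). Camera gave an adjusted p of 0.0106, and adjusted p = 0.655 with an estimated correlation. The list had a median of 0.30, and 0.07 on array 4. The inhibitor gene Nfkbia rose by 1.27 (SE 0.07, n = 4), the cytokine gene Il1a by 0.94 (SE 0.10), the chemokine gene Cxcl2 by 0.99 (SE 0.17) and the apoptosis inhibitor gene Birc3 by 0.77 (SE 0.19, above background on 3 arrays in either channel). On array 4 Cxcl2 read 0.34 and Birc3 0.03, and another Il1a probe read 1.37. In turn without arrays 1 to 4, 2, 2, 2 and 9 genes rose. The list was called with each array left out and under median centring. Cxcl2 (adjusted p 0.065, 0.058 and 0.064) and Birc3 (0.116, 0.107 and 0.123) were lost without array 1, 2 or 3.

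**Figure D2:**
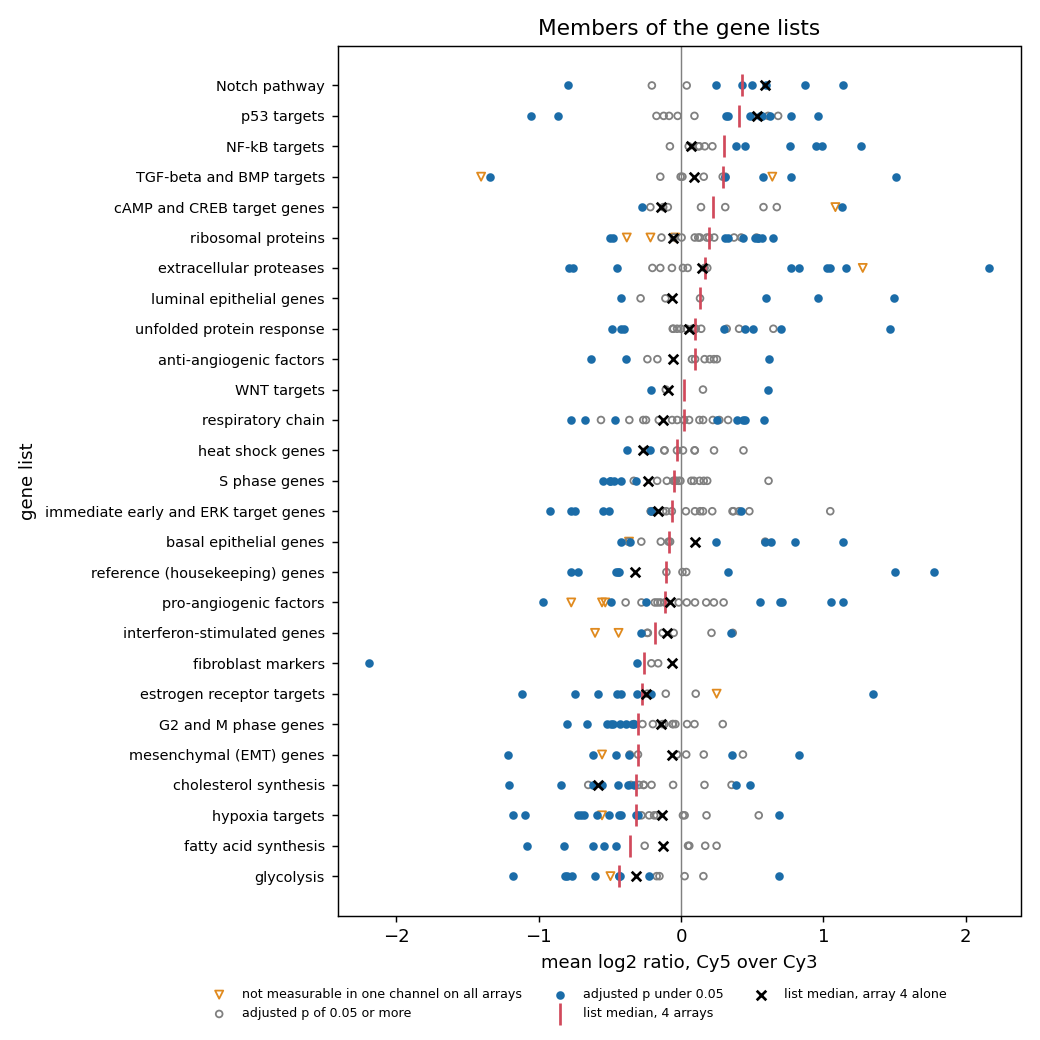
Mean log2 ratio of Cy5 over Cy3 over 4 arrays for each measured member of the 27 tested lists, sorted by list median. Filled points passed the adjusted threshold, open points did not, triangles were not measurable in one channel, the red bar is the list median and the cross is the median on array 4 alone; the hypoxia median is -0.31 over all arrays and -0.13 on array 4.

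Genes with a part in vessel growth went both ways. Of 23 measured pro-angiogenic factors 5 rose and 6 fell (12 changed when adjusted over the list alone), with a median of -0.11, a mean of 0.01 and a test direction of down. On array 4 the median was -0.08. The chemokine gene Cxcl1 rose by 1.06 (SE 0.13, n = 4) and Figf, also named vascular endothelial growth factor D, fell by 0.97 (SE 0.11). The Notch ligand gene Jag1 averaged 1.14 (SE 0.31) with 2.41 on array 4, and the VEGF co-receptor gene Nrp1 was at least 1.61-fold lower. Of 11 anti-angiogenic factors 1 rose and 2 fell (3 adjusted over the list alone), with a median of 0.10, and -0.06 on array 4. Thbs2 averaged -0.63 (SE 0.16) and read -0.02 on array 4, the related Thbs1 averaged -0.39 (SE 0.07, Cy5 above background on 3 arrays) and Cxcl10 averaged 0.61 (SE 0.17, above background on 3 arrays) with -0.06 on array 4. With arrays 1 to 4 left out in turn, 1, 1, 1 and 8 pro-angiogenic factors rose and 1, 1, 1 and 10 fell, and by limma 0, 0, 0 and 5 anti-angiogenic factors rose and 0, 0, 0 and 3 fell. The pro-angiogenic median was -0.05 without array 1 and -0.07 without array 2. Camera gave an adjusted p of 0.809 for both lists. Jag1 (adjusted p 0.085, 0.080 and 0.124), Nrp1 (0.090, 0.083 and 0.095), Thbs2 (0.125, 0.122 and 0.126), Thbs1 (0.073, 0.100 and 0.082) and Cxcl10 (0.143, 0.142 and 0.151) were lost without array 1, 2 or 3. The test direction turned for the anti-angiogenic list with the Feature Extraction ratio (0.780) and the deposited value table (0.779), and for the pro-angiogenic list under the strict filter (0.643) and without array 4 (0.937).

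Among 17 extracellular proteases 7 rose and 3 fell (10 adjusted over the list alone), with a median of 0.16, and 0.15 on array 4. The collagenase gene Mmp13 rose by 1.05 (SE 0.13, n = 4), beside Mmp3 and Plau above, and the gelatinase gene Mmp9 averaged 1.16 (SE 0.29, above background on 3 arrays) with -0.03 on array 4 and 0.64 at its other probe. Among 13 genes of the mesenchymal list 2 rose and 5 fell (7 adjusted over the list alone), with a median of -0.30, and -0.06 on array 4. The membrane protease gene Mmp14 rose by 0.83 (SE 0.08) with 0.29 at its other probe, the intermediate filament gene Vim averaged -0.62 (SE 0.12) and the fibronectin gene Fn1 averaged -1.22 (SE 0.19, Cy5 above background on 3 arrays). S100a4, counted among the falls, was saturated in Cy5 on every array and in Cy3 on 1. Its ratio is thus open upward, and on that 1 array open both ways. When arrays 1 to 4 were left out in turn, 6, 6, 5 and 8 proteases rose and by limma 1, 1, 0 and 4 fell, and 1, 1, 1 and 3 mesenchymal genes rose and 2, 1, 2 and 6 fell. The protease median was then 0.07, 0.10 and 0.10 without array 1, 2 or 4, and the mesenchymal median -0.18, -0.19 and -0.10. By camera the adjusted p was 0.143 for the proteases (0.0437 under median centring) and 0.561 for the mesenchymal list. Mmp9 (adjusted p 0.120, 0.109 and 0.127) was lost without array 1, 2 or 3, Vim without array 1 (0.072) or 2 (0.062) and Fn1 without array 1 (0.054) or 3 (0.061).

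Keratins and laminins were among the epithelial genes that changed. Of 7 measured luminal genes, out of 22 on the array, 3 rose and 1 fell (4 adjusted over the list alone), with a median of 0.13, and -0.06 on array 4. Krt18 rose 2.82-fold (SE 0.14 on the log2 scale, n = 4) and the transcription factor gene Gata3 rose by 0.96 on that scale (SE 0.14), with Krt19 at 0.60 (SE 0.15, above background on 3 arrays) and Xbp1 at -0.42 (SE 0.08). Without array 4 the luminal median was 0.71 (camera adjusted p 0.0665), and Krt8, named after its values were seen, averaged -0.11 (SE 0.59) with -2.56 on array 4. Of 14 measured basal genes, out of 15 on the array, 5 rose and 3 fell (11 adjusted over the list alone). They had a median of -0.08, a mean of 0.13 and a test direction of up, and on array 4 the median was 0.10. A larger share of the basal than of the luminal list was thus bright enough to test. The labelled line was examined only through a list of MCF-7 luminal markers in the tests of species given below. Of its 20 genes, 6 were well above background in Cy3 on every array. Its median log2 Cy3 signal relative to all probes was -0.31 (interval -0.83 to 3.68), against -0.23 for adipose tissue. By the medians the luminal list was thus not the brightest. The wide interval, and probes whose signals are not comparable, leave undecided whether the RNA came from that line. Lamb3 rose by 1.14 (SE 0.10), Lamc2 by 0.80 (SE 0.07) and Cd44 by 0.63 (SE 0.07), with Krt6b at 0.59 (SE 0.16) and 0.01 on array 4, with other probes of Lamc2 at 0.42 and of Cd44 at -0.10. The 3 falls, named after their values were seen, were Krt5, Krt14 and Krt17. These were saturated in Cy5 on 4, 3 and 3 arrays, which leaves their ratios open upward. Of 12 estrogen receptor targets 1 rose and 7 fell (9 adjusted over the list alone), with a median of -0.28, and -0.25 on array 4. The growth factor gene Areg rose by 1.35 (SE 0.10) and Fos fell by 0.74 (SE 0.08), with Car12 at -1.12 (SE 0.20) and Siah2 at -0.59 (SE 0.07, n = 3). In turn without arrays 1 to 4, 2, 2, 2 and 5 luminal genes rose and by limma 0, 0, 1 and 1 fell, 3, 3, 3 and 6 basal genes rose and by limma 1, 0, 0 and 6 fell, and 1, 1, 1 and 2 estrogen receptor targets rose and 1, 1, 2 and 8 fell. The basal median was then 0.0049, -0.03, -0.02 and -0.21. None of these lists passed in camera, with adjusted p of 0.337, 0.686 and 0.219 (the last over 11 genes, without Siah2), though the basal list did under median centring (0.0448). Krt19 (adjusted p 0.122, 0.116 and 0.128), Krt6b (0.134, 0.129 and 0.137), Car12 (0.070, 0.059 and 0.076) and Siah2 (0.061, 0.069 and 0.064) were lost without array 1, 2 or 3, and Xbp1 without array 1 (0.084) or 2 (0.096).

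Of 18 measured p53 targets 9 rose and 2 fell (12 adjusted over the list alone), with a median of 0.40, and 0.53 on array 4. Gadd45a rose by 0.96 (SE 0.08, n = 4) and Trp53inp1 by 0.77 (SE 0.07; 1.41 at its other probe), whereas Sesn1 fell by 1.05 (SE 0.15; -0.57 at its other probe) and Mdm2 by 0.87 (SE 0.11) with 0.05 at its other probe. Of 13 TGF-beta and BMP targets 5 rose and 2 fell (9 adjusted over the list alone), with a median of 0.29, and 0.09 on array 4. The activin subunit gene Inhba rose by 1.51 (SE 0.10), Id3 rose by 0.77 (SE 0.12), Tgfbi fell by 1.34 (SE 0.11) and Tgfb3 was at least 2.16-fold lower. Of 9 Notch pathway genes 6 rose and 1 fell (8 adjusted over the list alone), with a median of 0.43, and 0.59 on array 4, among them Hes1 at 0.87 (SE 0.14, n = 3), Notch2 at 0.59 (SE 0.16) with -0.03 at its other probe, and Notch3 at -0.79 (SE 0.16, Cy5 above background on 3 arrays). Of 4 WNT targets 1 rose and 1 fell (2 adjusted over the list alone), with a median of 0.02, and -0.09 on array 4. Lef1 averaged 0.61 (SE 0.15, Cy5 above background on 3 arrays) and Myc -0.21 (SE 0.06), which turned to 0.10 under median centring. Under that setting the median of all tested probes was 0.12, so Myc still lay below it. Other probes read 0.41 for Lef1 and -0.09 and 0.02 for Myc. With arrays 1 to 4 left out in turn, 5, 3, 3 and 11 p53 targets rose and 2, 2, 1 and 3 fell, and 3, 1, 2 and 7 TGF-beta and BMP targets rose and 1, 1, 1 and 3 fell. By limma 1, 0, 0 and 6 Notch genes then rose and 0, 0, 0 and 3 fell, and 0, 0, 0 and 1 WNT targets rose and 0, 0, 0 and 1 fell. The p53 median was 0.22 without array 4, and the WNT median 0.08, 0.05 and -0.05 without array 1, 2 or 4. In camera the 4 lists had adjusted p of 0.0548, 0.182, 0.260 (over 8 genes, without Hes1) and 0.974, and the test direction of the WNT list turned without a filter on dim probes (0.172), under the strict filter (0.643), with array weights (0.999) and without array 3 (0.953). The p53 list passed without array 1 (0.0297), 2 (0.0396) or 3 (0.0473), without a filter on dim probes (0.00826) and with the mean of all probes of a gene (0.0202). Sesn1 was lost without array 3 (0.055), Id3 without array 2 (0.051), Hes1 without array 2 (0.079) or 3 (0.079), and Tgfb3 (0.080, 0.069 and 0.087), Notch2 (0.123, 0.086 and 0.085), Notch3 (0.087, 0.082 and 0.091), Lef1 (0.118, 0.115 and 0.122) and Myc (0.146, 0.223 and 0.119) without array 1, 2 or 3.

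Among 23 immediate early and ERK target genes 1 rose and 6 fell (7 adjusted over the list alone), with a median of -0.07, and -0.16 on array 4. Egr1 fell by 0.92 (SE 0.13, n = 4), Egr2 averaged -0.77 (SE 0.16, Cy5 above background on 3 arrays) and Spred2 -0.55 (SE 0.09), with 0.12 at its other probe. Of 10 cAMP and CREB target genes 2 rose and 1 fell (5 adjusted over the list alone), with a median of 0.22, and -0.14 on array 4. The phosphodiesterase gene Pde4b rose by 1.13 (SE 0.15) and Ppargc1a averaged -0.28 (SE 0.07, Cy5 above background on 2 arrays). Other Pde4b probes read 0.78 and 1.38. When arrays 1 to 4 were left out in turn, by limma 0, 0, 0 and 9 immediate early genes rose and 2, 2, 1 and 9 fell, and 2, 2, 2 and 5 cAMP and CREB targets rose and 0, 0, 0 and 1 fell. The immediate early median was 0.0031, -0.02 and 0.08 without array 1, 2 or 4, and the cAMP median 0.34 without array 4. Camera gave adjusted p of 0.738 and 0.323. Egr1 was lost without array 3 (adjusted p 0.055), and Egr2 (0.086, 0.081 and 0.092), Spred2 (0.057, 0.063 and 0.061) and Ppargc1a (0.116, 0.172 and 0.143) without array 1, 2 or 3. The test direction of the immediate early list turned under median centring (0.826), with array weights (0.999) and without array 4 (0.904).

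Of 18 cholesterol synthesis genes 7 fell and 2 rose (9 adjusted over the list alone), with a median of -0.31, and -0.59 on array 4. Cyp51, a sterol demethylase gene, fell by 1.21 (SE 0.10, n = 4). Its probe, on chromosome 5 at 4087477 to 4087536, lay within the falling run of neighbouring genes given below. Lss fell by 0.85 (SE 0.09), Nsdhl averaged -0.62 (SE 0.11, Cy5 above background on 3 arrays) and Srebf2 -0.56 (SE 0.10). Other probes read -1.10 and -0.50 for Cyp51, -0.31 and 0.18 for Lss, -0.53 and -0.23 for Nsdhl and -0.50 and -0.29 for Srebf2. Of 10 fatty acid synthesis genes 5 fell and 0 rose by limma (6 adjusted over the list alone), with a median of -0.36, and -0.13 on array 4. The elongase gene Elovl6 averaged -1.08 (SE 0.18) and the desaturase gene Fads1 -0.62 (SE 0.10), with Srebf1 at -0.82 (SE 0.25) and Acss2 at -0.54 (SE 0.11; -0.23 at its other probe). In turn without arrays 1 to 4, by limma 2, 3, 3 and 10 cholesterol genes fell and 1, 0, 0 and 4 rose, and 0, 1, 1 and 6 fatty acid genes fell and 0, 0, 0 and 2 rose. The cholesterol median was -0.20 without array 4. Camera gave adjusted p of 0.104 and 0.251. The cholesterol list passed without array 2 (0.0404) or 3 (0.0420) and without a filter on dim probes (0.0252). Nsdhl was lost without array 1 (0.060) or 3 (0.065), Srebf2 without array 1 (0.067) or 2 (0.066), Elovl6 without array 1 (0.0503) or 3 (0.055), Fads1 without array 1 (0.052) or 2 (0.061), and Srebf1 (0.109, 0.107 and 0.110) and Acss2 (0.087, 0.096 and 0.097) without array 1, 2 or 3.

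Of 20 genes of the unfolded protein response 5 rose and 3 fell (8 adjusted over the list alone), with a median of 0.10, and 0.06 on array 4. The disulfide isomerase gene Pdia4 rose by 1.47 (SE 0.13, n = 4), Sdf2l1 averaged 0.70 (SE 0.11), Ddit3 0.51 (SE 0.10) and Edem1 -0.48 (SE 0.07), with 0.14 and 0.18 at its other probes. Of 11 heat shock genes 0 rose and 2 fell by limma (1 adjusted over the list alone), with a median of -0.03, and -0.27 on array 4. Hsp90ab1 averaged -0.38 (SE 0.08; Cy5 saturated on 1 array, which leaves it open upward), which turned to 0.18 under median centring and read 0.27 at its other probe, and Hspa1a -0.22 (SE 0.07), with -0.29 to 0.41 at its other probes. Of 10 interferon-stimulated genes 1 rose and 3 fell (5 adjusted over the list alone), with a median of -0.18, and -0.10 on array 4. Ifi27 was at least 1.47-fold lower, Ifit2 at least 1.17-fold lower with Cy3 above background on 3 arrays, Herc5 averaged 0.35 (SE 0.10) and Stat1 -0.28 (SE 0.06), with -0.28 to -0.05 at its other probes and -0.39 at that of Ifi27. With arrays 1 to 4 left out in turn, by limma 1, 1, 2 and 9 genes of the unfolded protein response rose and 0, 0, 2 and 3 fell, and 0, 0, 0 and 3 heat shock genes rose and 0, 0, 0 and 2 fell. Of the interferon-stimulated genes 0, 0, 0 and 2 then rose and 0, 0, 0 and 5 fell by limma. The first median was 0.18 without array 4, and the heat shock median -0.07 without array 2 or 3. The adjusted p in camera was 0.219, 0.809 and 0.397. The unfolded protein response passed under median centring (0.0448) and with the mean of all probes of a gene (0.0322). The direction of the heat shock list turned without background correction (0.856), under median centring (0.129), with array weights (0.991), with the mean of all probes (0.875) and without array 4 (0.772), and that of the interferon list under the strict filter (0.913). Only Pdia4 of these passed with each array left out. Sdf2l1 (adjusted p 0.052 and 0.056) and Edem1 (0.051 and 0.052) were lost without array 1 or 2, and Ddit3 (0.090, 0.095 and 0.094), Hsp90ab1 (0.089, 0.107 and 0.064), Hspa1a (0.166, 0.242 and 0.097), Ifi27 (0.094, 0.087 and 0.095), Ifit2 (0.110, 0.109 and 0.117), Herc5 (0.117, 0.171 and 0.151) and Stat1 (0.110, 0.130 and 0.099) without array 1, 2 or 3.

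Of 25 ribosomal protein genes 8 rose and 3 fell (12 adjusted over the list alone), with a median of 0.20, and -0.05 on array 4. Rpl5 rose by 0.54 (SE 0.07, n = 4; Cy5 saturated on 3 arrays), with Rplp0 at 0.57 (SE 0.11), Rps6 at 0.54 (SE 0.09) and Rpl37 at 0.65 (SE 0.20; Cy5 saturated on 2 arrays), which read -0.05 on array 4. Saturation in Cy5 leaves the ratios of Rpl5 and Rpl37 open upward. Of 24 respiratory chain genes 5 rose and 3 fell (9 adjusted over the list alone), with a median of 0.02, a mean of -0.01 and a test direction of up. On array 4 the median was -0.13. Sdha fell by 0.78 (SE 0.07; -1.08 at its other probe) and Ndufs1 by 0.67 (SE 0.10), with Ndufv1 at -0.47 (SE 0.08) and Cox6c at 0.58 (SE 0.17). Of 11 genes often taken as references 3 rose and 5 fell (8 adjusted over the list alone), with a median of -0.10, a mean of 0.07 and a test direction of down. On array 4 the median was -0.33. Actb, at a probe that the files place on chromosome X, rose 2.84-fold (SE 0.21 on the log2 scale) and read 0.50 at its other probe on that scale, Ywhaz rose as above, and B2m fell by 0.72 (SE 0.07) with -0.52 and 0.09 at its other probes. When arrays 1 to 4 were left out in turn, 3, 1, 1 and 13 ribosomal protein genes rose and by limma 2, 0, 0 and 4 fell, and by limma 1, 0, 0 and 10 respiratory genes rose and 2, 2, 2 and 7 fell. Of the reference genes 4, 2, 2 and 5 then fell. The respiratory median was -0.01, -0.04 and 0.13 without array 1, 2 or 4. By camera the 3 lists had adjusted p of 0.0622, 0.809 and 0.397. The ribosomal list passed without array 3 (0.0396) or 4 (0.0220), without background correction (0.00730), without a filter on dim probes (0.0252), under median centring (3.7e-06) and with array weights (0.0128). The respiratory list passed under median centring (0.0448), and its direction turned without array 1 (0.922) or 2 (0.868) and with the mean of all probes (0.875), as did that of the reference list under median centring (0.875). Rplp0 was lost without array 2 (0.076) or 3 (0.062), Rps6 without array 2 (0.071) or 3 (0.061), and Rpl37 (0.162, 0.162 and 0.145), Cox6c (0.118, 0.146 and 0.090) and Ndufv1 (0.051, 0.063 and 0.055) without array 1, 2 or 3.

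Markers of other cell types were rarely measured. Of the endothelial list 1 gene was measured, the podoplanin gene Pdpn, which rose by 1.37 (SE 0.15, n = 4; 1 adjusted over the list alone) and read 1.51 on array 4 and 1.33 at its other probe. Of 4 fibroblast markers 2 fell and 0 rose by limma (2 adjusted over the list alone), with a median of -0.26, and -0.06 on array 4: Acta2, given above, and Pdgfra at -0.31 (SE 0.08, Cy5 above background on 3 arrays). Of 2 leukocyte markers 1 fell, Cd68 at -0.45 (SE 0.08, Cy5 above background on 3 arrays), and 2 changed when adjusted over the list alone. The median on array 4 was -0.15. Camera gave an adjusted p of 0.0548 for the fibroblast list, and 0.0404 without array 2, 0.0420 without array 3 and 0.0427 under median centring. In turn without arrays 1 to 4, 1, 1, 1 and 4 fibroblast markers fell, and by limma 0, 0, 0 and 2 leukocyte markers. Pdgfra (adjusted p 0.125, 0.128 and 0.123) and Cd68 (0.075, 0.087 and 0.078) were lost without array 1, 2 or 3.

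Over all 27 tested lists, camera called 3 lower and 1 higher, and with an estimated correlation it called 0. Of the lists called lower, hypoxia targets and glycolysis share members. Camera called 7 lists without array 2 and 8 without array 3. The test fry asks whether the genes of a list move on balance one way and does not compare a list with other genes. It passed for 11 lists. Its adjusted p was 0.00645 for the extracellular proteases, 0.00918 for the TGF-beta and BMP targets and the fibroblast markers, 0.0185 for the reference genes, 0.0227 for the hypoxia targets and 0.0410 for the mesenchymal list. It was 0.0184 for glycolysis, the NF-kB targets, the p53 targets, the estrogen receptor targets and fatty acid synthesis. The G2 and M phase genes, called by camera, did not pass in fry (0.0580). Asked for change in either direction, fry passed for 26 lists, all but the anti-angiogenic factors (0.0661).

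The median standard deviation of log2 signal between arrays, over 12080 probes, was 0.19 in Cy5, which held the 4 samples, and 0.08 in Cy3, which held the same pool each time. The median variance in Cy5 was 5.08 times that in Cy3, 3.46 times without array 4 and 9.96 times with the processed signals of Feature Extraction. With 1 dye orientation, differences between the samples were not separated from differences between the dyes.

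The 6 falls named on chromosome 5 lay in a run of neighbouring genes. Between positions 3535293 and 17285439 of mm7, 29 of 36 genes fell, 3 rose and 21 fell at least 2-fold, with a median log2 ratio of -1.16 over the 4 arrays and -0.68 on array 4. The cell cycle kinase gene Cdk6 at the start of the run fell by 1.17 (SE 0.08, n = 4), and the guidance gene Sema3c near its end rose by 0.49 (SE 0.08). On chromosome 10, between 112431785 and 119776770, 22 of 27 genes fell and 1 rose, with a median of -0.68, and -0.53 on array 4. Helb fell by 1.39 (SE 0.08), Nup107 by 1.23 (SE 0.10), Tbc1d15 by 1.22 (SE 0.06) and Mdm2 as above, whereas the channel subunit gene Kcnmb4 rose by 0.80 (SE 0.06). No random gene order gave a window as low as either run's lowest. The permutation p was 0.001 for each run, the smallest that 1000 orders can give. The scan marks runs by these same orders, so that p is no separate test of chance. The chromosome 10 run was not found with windows of 5 genes, and its median was -0.41 under median centring.

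**Figure D3:**
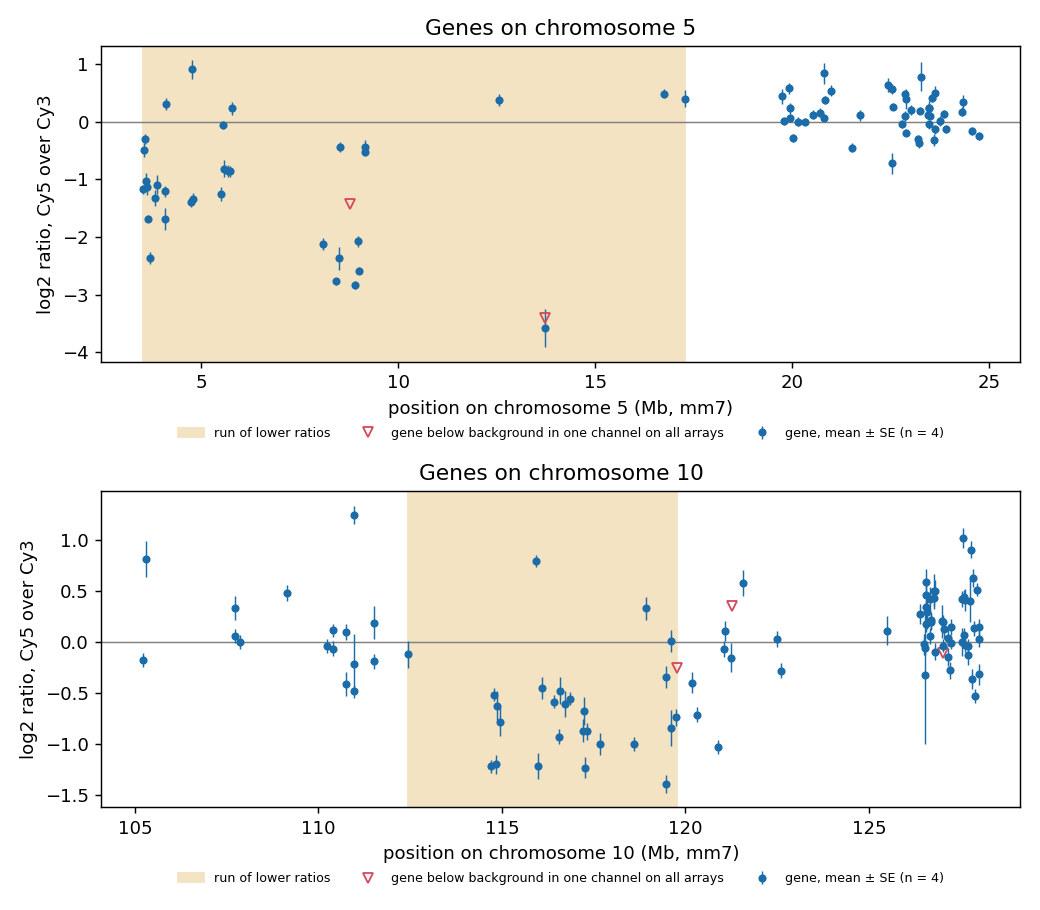
Mean log2 ratio of Cy5 over Cy3 over 4 arrays, with its standard error, for genes by position in Mb on mouse chromosomes 5 and 10 (mm7). Shading marks the runs of lower ratios, with medians of -1.16 and -0.68. Open triangles mark genes not well above background in one channel on any array. They are drawn at their fitted ratio, which is not the at-least fold.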

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

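The correlation of array 4 after removal of a trend with GC content and brightness and the comparison of Cy3 deviations were chosen after the result was seen, whereas the test on the brightest probes was set beforehand. For 118 named genes, 30 lists, 5 runs of neighbouring genes and 6 array values, the gap between the most extreme array and its nearest neighbour was divided by the whole range of the 4 arrays. Chance takes about 1 in 20 such values past the critical value if they are independent and normal. Past it lay 30 of 159, with array 4 the extreme array for 27. By kind these were 27 of 118 genes, 0 of 30 list medians, 1 of 5 runs and 2 of 6 array values. The items share the same 4 arrays and overlap in genes, and many genes were picked by their values. The rate of 1 in 20 is thus only a rough guide.

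Array 4 stood apart from arrays 1 to 3 for 25 genes. Toward 0, with this share of the range in parentheses, lay the cytokine gene Tslp (0.979), the gelatinase gene Mmp9 (0.971), Sesn1 (0.944), Ddit3 (0.942), Tgfb3 (0.905), Nrp1 (0.888), Birc3 (0.870), Cxcl10 (0.869), Slc9a2 (0.868), Krt18 (0.868), Bnip3 (0.866), Aldoc (0.864), Lef1 (0.845), Emb (0.844), Actc1 (0.840) and Egr2 (0.840). Mmp9 read -0.03 on array 4 against 1.54 on array 3, and Bnip3 0.11 against -0.91. Farther from 0 lay Abcb1b (0.920), the lipid regulator gene Srebf1 (0.908), Actb (0.903), Tgfbi (0.898), Rrm1 (0.893), Elovl6 (0.877), Sri (0.870), Ube2c (0.851) and Ccna2 (0.849). Srebf1 read -1.82 on array 4 against -0.42 on array 3, and Actb 2.37 against 1.16. Fos on array 1 (0.859) and Pde4b on array 3 (0.856) were also past the critical value, with log2 ratios of -0.97 and 1.69. The median of the falling run on chromosome 10 stood apart on array 4 (0.842), as did its 382 spots marked as outliers by the scanner software (0.910). The median Cy5 signal of array 3 stood apart (0.879), at 1406 against 1031 on array 2.

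For the distance of array 4, dim Cy5 signal was argued against as the whole cause, since the correlation with arrays 1 to 3 among the brightest probes was 0.490 (95% interval 0.466 to 0.517), under the 0.6 set beforehand. After removal of a trend with GC content and brightness it was 0.427 (0.412 to 0.444). A different Cy5 RNA alone was argued against as the whole cause by the Cy3 channel, which held the same pool, where the variance of the deviation was 0.129 on array 4 and 5.87 times (5.29 to 6.24) the highest of arrays 1 to 3. That comparison replaced a ratio of Cy5 to Cy3 deviation variance, 1.90 on array 4 and 2.11 to 2.47 on arrays 1 to 3, which could not tell the explanations apart. A fault of hybridisation or labelling in both channels and a difference between the cultures, on top of each other, stay open and untested.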

How the results depend on the processing

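The windows of 20 and 5 genes, the medians of the 2 runs under each setting and the channel spread with single arrays left out were chosen after the result was seen. Median centring in place of loess moved most. It called 0 probes and 0 changes of 2-fold in limma (3258 at an unadjusted p under 0.05, smallest adjusted p 0.0770), with a median standard deviation per probe of 0.41 against 0.17 and a median log2 ratio of all tested probes of 0.12. All 120 named genes were then short of the threshold, and Hsp90ab1 (0.18) and Myc (0.10) turned above 0, of which only Hsp90ab1 lay above that median. S100a4 came to 0.039, but its Cy5 saturation on every array leaves that sign without meaning. Camera under median centring called 8 lists, 6 up and 2 down: G2 and M phase genes (0.189) and glycolysis (0.119) were lost, hypoxia targets (0.0308) and NF-kB targets (0.00638) stayed, and ribosomal proteins (3.7e-06), extracellular proteases (0.0437), basal genes (0.0448), the unfolded protein response (0.0448), the respiratory chain (0.0448) and fibroblast markers (0.0427) passed. These calls used the fixed inter-gene correlation of 0.01. An estimated correlation, run with the main setting only, called 0 lists. Why median centring moved these results was not tested.

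The Feature Extraction ratio and the deposited value table each gave 1199 changes of 2-fold in place of 313, with 535 up and 664 down against 189 up and 124 down, and channel spread was 9.96 with processed signals against 5.08. Array weights of 0.955, 11.6, 0.832 and 0.108 for arrays 1 to 4 gave 13922 calls and 510 changes of 2-fold, and treat gave 65. Without a filter on dim probes 7 lists passed in camera, with p53 targets (0.00826), cholesterol synthesis (0.0252) and ribosomal proteins (0.0252) gained. With the main filter and an estimated correlation 0 lists passed. The mean of all probes of a gene, run for the lists only, gave 6 of them, with the unfolded protein response (0.0322) and p53 targets (0.0202) gained. Ribosomal proteins were gained without background correction (0.00730) and with array weights (0.0128). The causes were not tested. Leaving out 1 array gave 1013 to 10676 calls, 181 to 499 changes of 2-fold, 5 to 8 lists and a channel spread of 3.46 to 5.69. All of the 5970 calls were kept without array 4, and 1273, 1013 and 1122 without arrays 1, 2 and 3. Without array 1, 2 or 3, 55, 56 and 58 of the 120 named genes lost their call, and without array 4 none did, with fewer arrays in each fit. The chromosome 5 run had a median of -1.54 with the Feature Extraction ratio, and the chromosome 10 run -0.86 with it and -0.41 under median centring. Windows of 5 genes gave 3 runs in place of 5.

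No background correction, an offset of 0, the strict filter and another variance model kept the counts of calls, 2-fold changes and lists within 1.5 times. Removal of a GC trend was run for the 2-fold changes only and kept that count within 1.5 times. Aquantile scaling leaves log ratios as they are and so tests nothing. The alternative restricted to probes that match a human transcript in full was not run, because human transcripts were not used here. No paired analysis was possible because the labels give 1 group. Signal over background limited Cy5 most on array 4, with 30.5% of probes well above it.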

Other observations

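The scan along the chromosomes and its tests were chosen after the result was seen, while the tests of species were set beforehand. Genes of 3 further runs of neighbours differed between the channels. On chromosome 15, between 73837401 and 75740278 of mm7, 7 of 14 genes fell and 1 rose, with a median log2 ratio of -0.47, and -0.10 on array 4. They included Ly6a at -1.01 (SE 0.07, n = 4), Ly6e at -0.91 (SE 0.19), Ly6c at -0.85 (SE 0.07), Lynx1 at -0.81 (SE 0.09) and Ly6d at -0.71 (SE 0.19), which with Slurp1, whose product is secreted, belong to the Ly6 family. On chromosome 9, between 5223467 and 7960454, 6 of 15 genes rose and 5 fell, with a median of 0.16, and 0.12 on array 4. The neighbouring metalloprotease genes Mmp13, Mmp3 and Mmp10 rose, the last by 1.03 (SE 0.07), with Mmp1a at 0.62 (SE 0.15; well above background on 2 arrays in Cy3 and 3 in Cy5), whereas Casp12 fell by 0.75 (SE 0.16) and Yap1 fell by 0.47 (SE 0.12). Another stretch of chromosome 5, from 90574633 to 91129390, held 6 of 10 genes that rose and 0 that fell in limma, with a median of 0.63 (0.58 with genes measured in 1 channel at their bound), and 0.32 on array 4. Among them were the chemokine genes Cxcl1 and Cxcl2 and the growth factor genes Areg and Ereg, the last at 0.71 (SE 0.11). Permutation p was 0.002, 0.006 and 0.018, from the same random orders that marked the runs. The runs on chromosomes 15 and 9 were not found with windows of 20 or 5 genes, and the rising run on chromosome 5 was not found with windows of 5 genes or without array 1, 2 or 3.

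For the falling runs on chromosomes 5 and 10, shared probe sequence was argued against, since 0% of their genes had a probe sharing 20 bases with another of the run. No random order of the 1000 gave a window as low, a permutation p of 0.001. The scan picked the runs by those same orders, so a small p was fixed and is no separate test of chance order. A difference in copy number between the cells behind the dyes is a candidate explanation that stays open. Further probes of the same genes, which had not set the runs, lay below 0 in 77.8% of 27 cases on chromosome 5 (95% interval 57.7 to 91.4) and 90% of 20 on chromosome 10. Of all placed genes 52.2% lay below 0 at their brightest probe. The first interval reaches under the 60% required. Several further probes can share a gene, so the interval takes dependent probes as independent. That test replaced the share of genes below 0 in the chromosome 5 run, 83.3%, which the choice of the run fixes in part. Regulation of neighbouring genes together would look alike, and DNA was not analysed here.

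Signals on mouse probes from RNA labelled human were weighed with 13 marker lists. Of 22 genes on the array from a list of rodent genes, 13 were well above background in Cy3 on every array. These were Ccl9, Ifi203, Ifi204, Ifi205, Ly6a, Ly6c, Rhox5 and the histocompatibility genes H2-D1, H2-K1, H2-Q7, H2-T10, H2-T22 and H2-T23. They made up 59.1% of genes, against 35.8% of all probes. The list had 35 probes, so a gene could pass at any of several, and the shares are not alike in unit. The median log2 Cy3 signal of the rodent list lay 2.24 above that of all probes (95% interval -0.19 to 4.87). It lay 0.46 above without histocompatibility genes, a value not among the tests set beforehand. Probes of 1 gene correlated in brightness with Spearman's rho of 0.464 (0.446 to 0.480) across 8845 genes, which are not independent. Genes above background numbered 6 of 20 on the MCF-7 luminal list (Ccnd1, Ctsd, Gata3, Krt18, Krt8 and Xbp1), 2 of 8 for muscle, 2 of 9 for macrophage, 2 of 10 for fibroblast, 1 of 10 for brain, 1 of 8 for adipose tissue, 1 of 9 for lymphoid cells, and 0 of 9 for pituitary, 0 of 10 for liver, 0 of 7 for kidney, 0 of 8 for pancreas and 0 of 7 for endothelium. The median log2 Cy3 signal relative to all probes was -0.31 for the luminal list (-0.83 to 3.68) and -0.23 for adipose tissue (-0.89 to 1.07). The sign set beforehand for human RNA was a rodent median at or below that of all probes and a brightest luminal list. By the medians neither part was met, though the wide intervals leave both parts undecided. Of the signs set for a mouse sample, the rodent median met its limit and the correlation fell short. Probes not above background were kept in that correlation and could lower it, so its shortfall is no sign against mouse RNA. Krt5, Krt14, Krt17 and S100a4, picked after their values were seen, were saturated in Cy5 on 4, 3, 3 and 4 arrays. By the tests set beforehand, human RNA bound to mouse probes and RNA of a mouse sample were not told apart. Signals of different probes are not comparable. The interval of the rodent median spans the limits set for both, and the correlation lies between the limits set for the mouse sample. The rodent list holds mouse genes without a human orthologue of the same sequence. Of its 22 genes on the array, 13 were above background in Cy3 on every array and 12 in Cy5. These counts lean toward mouse RNA, but whether human RNA can bind those probes was not tested.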
